A study of Bombyx mori with 10 samples.

How the data were processed

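The samples were 10 pools of whole brains from adult male silkmoths raised at 25 degrees in 12 h of light and 12 h of dark, 10 brains per pool. Per the labels' protocols, 5 pools came from males exposed to female odor for 30 min and 5 from untreated males, total RNA was treated with DNase, and cyanine 3 cRNA was made from 0.4 ug of RNA by linear amplification. Nothing in the labels ties a pool of one group to a pool of the other beyond a replicate number. Groups and replicate numbers were taken from the source names, and the titles carry another numbering.

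The arrays were hybridised with 1 colour and read with Agilent Feature Extraction 9.1.3.1, per the file headers and the submitters' processing notes. The deposited spot intensity values are processed signals, background-subtracted and corrected for spatial trend by the software, per the file headers, on a linear scale and not normalized between arrays. The deposited value table held the same intensity numbers: the largest difference from the processed signal was 0, so its scale is linear and it is neither centred nor a ratio. Its column medians lay between 164.4 and 215.1. Each array had 15744 spots, of which 536 were controls and were left out. Each of the other 15208 probes was a 60-mer with 1 spot. Between 2 and 18 spots per array carried an outlier flag and were set aside. The array median of the processed signal lay between 180.0 and 236.7 intensity units. Low signals limit precision, since 9.25% to 13.3% of probes per array had a surrogate value in place of a signal below background.

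Log2 processed signals were reduced by each array's 75th percentile over the non-control probes, and a log2 signal in the text is this value. Probes were kept where at least 5 of the 10 arrays had them well above background, which left out 2886, and 2 more were left out because of outlier flags, so 12320 were tested. Stimulated and control arrays were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. A difference is stimulated minus control on the log2 scale, with limma's moderated standard error and 95% interval. Exact permutation tests used every split of the 10 arrays into 5 and 5 and were two-sided, with 0.00794 as the smallest p. Tested probes well above background on no array of a group numbered 0, so no bound was needed. The p-values measure the spread between these pools.

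Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, with fry, and with an exact permutation test of the per-array list mean. Adjustment was over the lists of a kind, and members were also adjusted over the list alone. A list needed 3 tested probes for a set test. Before the data were examined, 18 lists of gene name patterns were fixed; the files gave truncated family names, so 12 of these matched no probe: activity-regulated genes, nuclear receptors and ecdysone genes, amine and fast transmitter genes, neuropeptides, clock genes, ribosomal proteins, oxidative phosphorylation, and markers of antenna, glia, fat body, haemocytes and corpora allata. The further 24 lists by family number hold 618 probes, 456 of them tested. A family is not a gene, so each probe was treated as its own feature, and averaging the probes of a gene was not run. Running fry and camera with an estimated correlation under every alternative was added after the data were seen. Of the names in the files, 0 matched the gene table used here.

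The rule for named probes was set before the data were examined. It took every Hr38 probe, the changed probes of largest size, and, as fewer than 20 passed, the probes of smallest p up to 20, given as values that did not pass. From each fixed list it took members that passed, the 2 of smallest p and the brightest. From the lists by family number, members that passed and the 2 of smallest p were taken, and the text gives some of these. Of the 20, probes without a gene or family name are described in the report for at most 2 higher and 2 lower, and the closing section names 3 more, CUST_2034, CUST_4457 and CUST_10691, each singled out by its values. The P450, calponin and further muscle probes described after the report, and CUST_2173, CUST_2360 and CUST_328, were chosen after their values were seen.

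The fit was tested on simulated data made from the measured probe means, slide effects and residual spread of 12320 probes, with 200 probes changed in each of 5 runs, 100 by 2-fold and 100 by 1.5-fold. In 5 further runs no probe was changed. Residuals were drawn independently for each probe in all runs, so correlation between probes was absent. Without the block 2.44% of calls were false on average, and with slide as a block 5.92%. In 200 simulated lists of 10 probes camera called 3.50% at an unadjusted p under 0.05 with no shift and 100.0% with a shift of 0.3. Members of those lists were uncorrelated, while the estimated correlation of the fixed antimicrobial list was 0.60. These shares therefore do not hold for lists of correlated probes.

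Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter, a filter on all 10 arrays, slide as a block, replicate number as a block in both numberings, a trended robust variance, array weights, the value table, each array left out, an adjusted p under 0.1, and a 1.5-fold minimum. Normexp started from the mean spot signal and the local background, so it left out the software's spatial correction. Same-numbered pools were compared by the correlation of their deviations from the group means. Slides and scan batches coincided. No 2 arrays held the same values, as the highest correlation between arrays was 0.994 across probes. Figures were drawn with matplotlib 3.10.9.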

Results

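Transcript levels were measured in whole brains of adult male silkmoths (Bombyx mori) on a custom 1-colour oligonucleotide array. Males of this species respond to odor released by females, which holds the sex pheromone. In 5 samples the males had been exposed to female odor for 30 min before dissection, and in 5 samples the males were untreated. Each sample was a pool of 10 brains, so the spread between samples is a spread between pools. Of the 15208 probes that are not controls, between 78.1% and 83.2% were well above background on an array, and no spot was saturated. The number of arrays limits the precision. The files name 2452 probes by an InterPro protein family and 11560 by a sequence cluster, and 1196 carry no name. The text therefore names a probe by its family and ID, and no genomic position is given.

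The arrays lay on 2 slides. Slide 1 held control replicates 1, 2 and 3 and stimulated replicates 1 and 2, and slide 2 held control replicates 4 and 5 and stimulated replicates 3, 4 and 5. The first principal component, with 33.4% of the variance, separated the slides, and the second, with 20.6%, spread arrays within each slide. With group in the model, 5366 of the 12320 probes tested differed between slides at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 3255 of them brighter on slide 2. The median correlation of arrays of the same group was 0.986 across probes, and that of arrays of different groups was also 0.986. Controls took the first positions of each slide and stimulated samples the last, so group and position overlapped only at the position that held control replicate 3 on slide 1 and stimulated replicate 3 on slide 2.

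**Figure D1:**
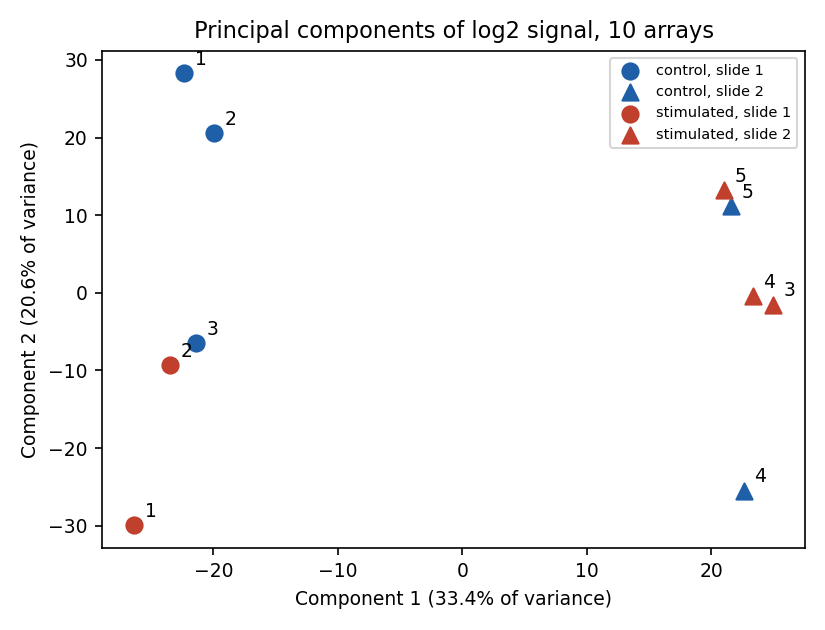
Scores of the 10 arrays on the first 2 principal components of the log2 signals (arbitrary units), which hold 33.4% and 20.6% of the variance. Colour gives the group, the symbol gives the slide and the number gives the replicate. The slides stand apart on the first component, and on each slide the groups are not ordered the same way on the second.

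The comparison of stimulated with control brains asked which transcripts changed within 30 min of female odor, and the series title names the nuclear receptor gene Hr38 as one induced by neural activity. No probe is named Hr38 in the files, and the gene table used here holds no row of that name, so no Hr38 value is given. No probe of the brain array passed the test: of 12320 probes, 0 reached an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.980. At an unadjusted p under 0.05 there were 490 probes, 287 higher and 203 lower after odor. The same fit, which leaves the slide difference in its error, gave a mean of 273 in 5 simulated data sets in which no probe changed, and evenly spread p-values would give 616. With slide as a block, 0 probes passed, the smallest adjusted p was 0.111, and 1047 probes had an unadjusted p under 0.05, 572 higher and 475 lower, against a mean of 621 in those simulated data sets. The simulated probes varied independently, so these means do not show how widely such counts vary among correlated probes. The 95% interval of the difference lay within 2-fold in both directions for 11330 probes, or 92.0%, and within 1.5-fold for 9382 probes, or 76.2%. On simulated data of this design, 74% of probes changed by 2-fold and 46.4% of those changed by 1.5-fold were recovered without the block, and 85.4% and 71.2% with it. Each of these runs held 200 changed probes. The adjusted threshold is harder to pass where fewer probes change, so these shares do not hold for a response of a few transcripts.

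**Figure D2:**
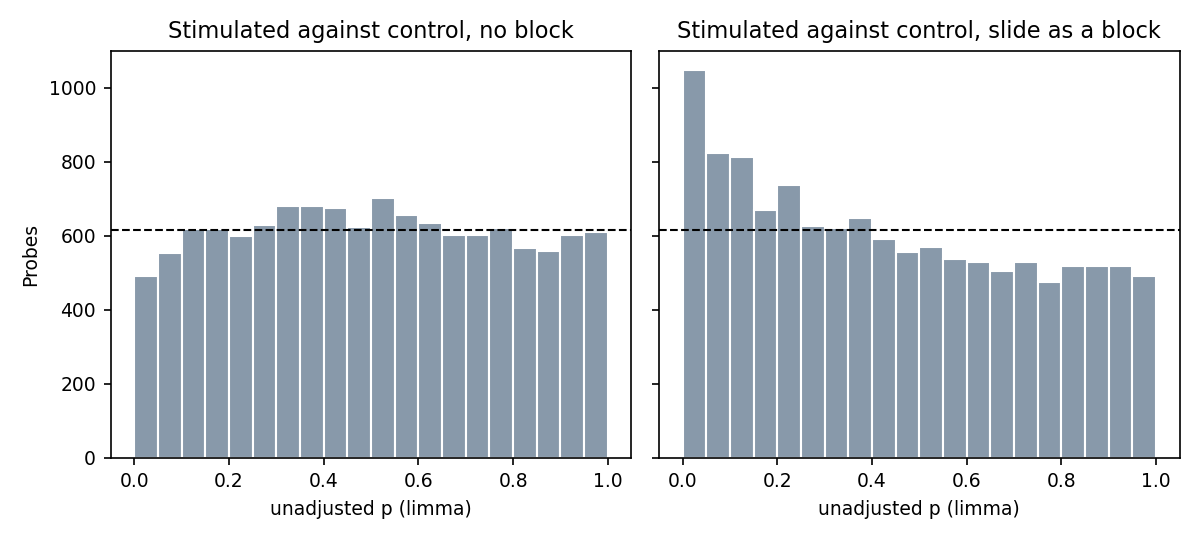
Histograms of the unadjusted limma p of 12320 probes for stimulated against control brains, in 20 bins, without a block on the left and with slide as a block on the right. Bars give probes per bin and the dashed line the 616 probes per bin of evenly spread p-values. The lowest bin holds 490 probes without the block, where 5 simulated data sets in which no probe changed gave a mean of 273, and 1047 with it, where they gave 621. The simulated probes varied independently of each other.

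None of the 20 probes with the smallest p passed, and their values are given as such. Of these, 17 were higher and 3 lower after odor, all 20 had the same sign on both slides, and 5 carry a family name. Their choice by small p on these same arrays favours a shared sign. A probe of the chitin binding family (CUST_1009) had a log2 signal of -5.73 ± 0.13 (SD, n = 5) in control and -5.33 ± 0.12 (SD, n = 5) in stimulated brains, a difference of 0.40 with a standard error of 0.08. An insect cuticle protein probe (CUST_272) differed by 0.41 with a standard error of 0.09, by 0.23 on slide 1 and 0.58 on slide 2. The largest difference of the 5 was that of a UDP-glucuronosyltransferase probe (CUST_2852), a family that attaches sugar groups to small lipophilic molecules: -3.21 ± 0.65 (SD, n = 5) in control and -1.97 ± 0.38 (SD, n = 5) in stimulated brains, 2.37-fold higher, with 1.78 on slide 1 and 0.73 on slide 2. A Ras family GTPase probe (CUST_2444) was higher by 0.44 with a standard error of 0.11. A probe of the transmembrane amino acid transporters (CUST_843) was lower, with a difference of -0.37 and a standard error of 0.09. With normexp background correction, the differences of CUST_1009, CUST_272, CUST_2444 and CUST_843 were 0.12, 0.20, 0.29 and -0.12. In each of these 5 probes the groups did not overlap, which has an exact permutation p of 0.00794, the smallest the exact test can give with 5 arrays against 5. Over all probes 96 showed such a separation, or 0.779%, and chance gives 0.794% if the slides are ignored. The other splits that keep the numbers of stimulated arrays per slide separated a mean of 44.1 probes and at most 180, and 4 of the 100 such splits, the real one included, separated as many.

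**Figure D3:**
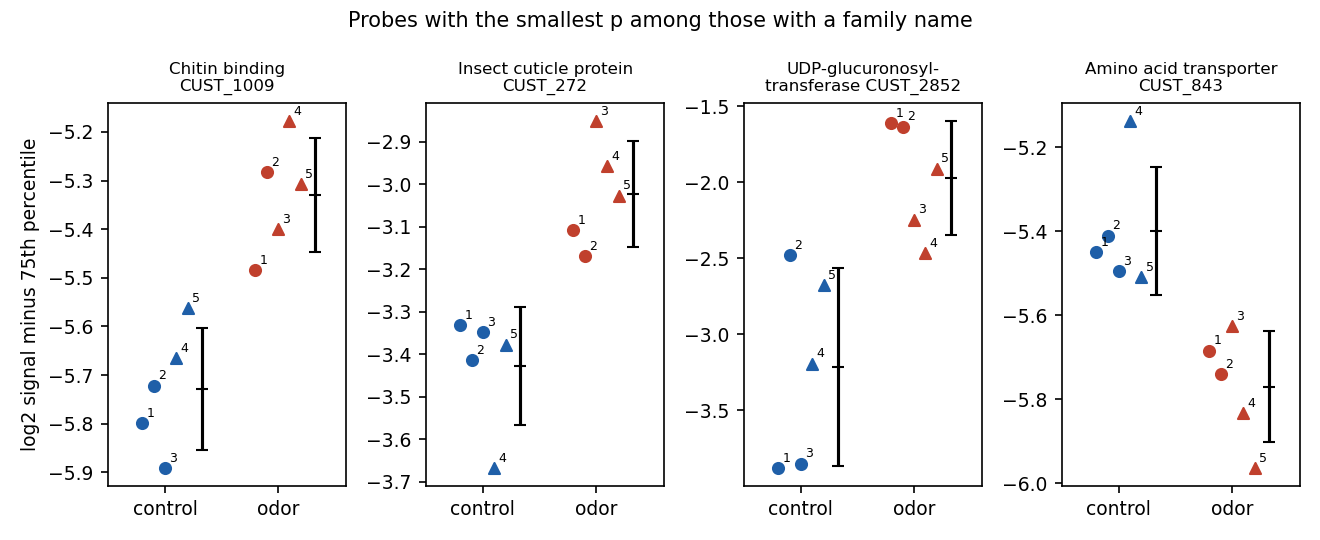
Log2 signal minus the 75th percentile of the array for 4 family-named probes with small p, with a point per array numbered by replicate (circles slide 1, triangles slide 2) and group mean ± SD in black, n = 5 per group. Control and stimulated points do not overlap in any panel, and no probe passed the adjusted threshold over 12320 probes.

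The other 15 of the 20 carry only sequence cluster names. The probe with the smallest p of all (CUST_8288, sequence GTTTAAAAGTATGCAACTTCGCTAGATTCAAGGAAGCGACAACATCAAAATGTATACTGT) had a log2 signal of -2.18 ± 0.14 (SD, n = 5) in control and -1.69 ± 0.07 (SD, n = 5) in stimulated brains. The difference was 0.48 with a 95% interval from 0.31 to 0.66, and it was 0.43 on slide 1 and 0.53 on slide 2. CUST_10630 was higher by 0.37 with a standard error of 0.08. Of the 3 lower probes, CUST_3317 (sequence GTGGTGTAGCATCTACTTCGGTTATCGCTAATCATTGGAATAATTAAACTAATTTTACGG) differed by -0.36 with a 95% interval from -0.55 to -0.17. CUST_7127 differed by -0.26 with a standard error of 0.06. With normexp these differences were -0.14 each.

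Of the 18 gene lists fixed before the files were opened, 6 matched any family name and 3 had enough tested probes for a set test. Probes of cuticle and chitin proteins, a sign of head capsule or trachea in a dissected brain, had a mean difference of 0.13 over 9 probes (camera adjusted p = 0.238, and adjusted p = 0.317 with an estimated correlation). Of the 9, 6 were higher and 3 lower, with a median of 0.0097, and the mean was 0.050 with normexp and 0.075 with no filter. The per-array mean of this list gave an exact permutation p of 0.0397, adjusted to 0.119 over the 3 lists. By limma's rotation test fry the list passed upward (adjusted p = 0.0275). Fry asks whether the members move one way on balance and does not compare them with other probes. Over 27 alternatives the fry adjusted p ran from 0.0120 to 0.781, and 14 passed. Of the 14, the trended robust variance and the value table repeat the main fry fit by construction. Slide as a block with the trended robust variance likewise repeats slide as a block. The fry call was not made with normexp, alone or with slide as a block, quantile normalization, median centring, no filter, either replicate block or array weights, nor without control replicate 4 or stimulated replicate 2 or both control replicate 4 and stimulated replicate 5, nor on either slide alone. Of its 9 probes 0 passed over all probes and 1 rose when adjusted over the list alone, CUST_1009 (limma adjusted p = 0.00694), a call not made with normexp or on either slide alone. The chitin binding probe CUST_420 differed by 0.30 with a standard error of 0.27, and the brightest of the list, CUST_3270, by -0.04 with a standard error of 0.10. The 4 probes of synaptic proteins and channels had a mean difference of 0.01, a median of -0.00017 and a camera direction that was down (adjusted p = 0.730), and the mean was negative with normexp, quantile normalization or median centring. Among them, a dynamin probe (CUST_1164) differed by -0.11 and synapsin probes, of a protein that tethers synaptic vesicles, by 0.15 (CUST_307) and 0.00 (CUST_308). The 5 antimicrobial peptide probes were all lower in the mean, by -0.60 (camera adjusted p = 0.257, exact permutation p = 0.548), but the list mean differed by -2.51 on slide 1 and 1.31 on slide 2. Without control replicate 4 the list passed camera at the preset correlation (adjusted p = 0.0341; 0.00205 to 0.971 over 26 alternatives) but not with an estimated correlation (adjusted p = 0.327). None of these passed alone: a cecropin probe (CUST_18) differed by -0.96 with a standard error of 0.69, and the brightest, an attacin probe (CUST_2737), by -0.92 with a standard error of 1.46. Lists of 2 probes had no set test: chaperonins differed by -0.13 (CUST_3282) and 0.03 (CUST_1205), arrestins by 0.03 (CUST_1430) and 0.00 (CUST_3597), and the muscle proteins troponin by 0.89 (CUST_1030, standard error 0.39) and 0.55 (CUST_1029, standard error 0.49).

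Because few names matched, 24 further lists were built from family numbers after the names had been seen and before any signal was compared. Of the 22 with at least 3 tested probes, 0 passed camera (smallest adjusted p = 0.421; with an estimated correlation, smallest adjusted p = 0.734), 0 passed fry (smallest adjusted p = 0.712), and of their member probes 0 passed over all probes. Nuclear receptors, the family Hr38 belongs to, had 5 tested probes, 4 higher and 1 lower, with a mean difference of 0.23 that was 0.26 on slide 1 and 0.25 on slide 2. The mean was 0.074 with normexp and 0.063 over the probes above background on all 10 arrays. The exact permutation p of the list mean was 0.0159, adjusted to 0.349 over 22 lists, and camera gave an adjusted p of 0.421. The mean rested mostly on a dim ligand-binding domain probe (CUST_2962), well above background on 2 control and 5 stimulated arrays, which was higher by 0.90 with a standard error of 0.31 and did not pass over the list alone (adjusted p = 0.0834). With normexp its difference was 0.15, and without control replicate 2 or stimulated replicate 4, as with replicate number as a block or array weights, 1 member of the list passed over the list alone. The second, a DNA-binding domain probe (CUST_715), differed by 0.14 with a standard error of 0.10. Transcription factors of the bHLH and PAS families with photolyases, which include circadian clock proteins, had 7 of 9 probes higher and a mean difference of 0.10 (camera adjusted p = 0.421), led by a PAS domain probe (CUST_3470) at 0.27 with a standard error of 0.09, and at 0.078 with normexp. C2H2 zinc fingers had 55 of 94 probes higher (mean 0.03), led by CUST_1575 at 0.37 with a standard error of 0.10. Basic leucine zipper factors, the family of Fos and Jun, had 5 of 6 probes lower (mean -0.06), and the first of them, CUST_1230, differed by -0.12. Homeobox and fork head factors had a mean of -0.01 while camera placed them up (adjusted p = 0.859), and the mean was positive with normexp.

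Of the 74 probes named by rule, 34 had a difference over 1.5 times smaller with normexp and 3 one over 1.5 times larger. Normexp draws dim signals together, but it also left out the software's spatial correction. Some probes that were not dim moved too, such as CUST_1497 (log2 signal 1.98 in control brains), at -0.37 as reported and -0.11 with normexp. What each step contributed was not tested. Families of neuronal signalling showed mean differences close to 0, and none of their probes passed over its list alone in the main fit. In other settings some did. An EF-hand probe passed without control replicate 4, without both control replicate 4 and stimulated replicate 5, and on slide 1 alone. A G protein-coupled receptor passed on slide 1 alone and a neuropeptide probe without stimulated replicate 4, and array weights called members of several of these lists. G protein-coupled receptors had 17 of 28 probes lower (mean -0.04), and a rhodopsin-like receptor (CUST_2323) was higher by 0.27 in the mean but differed by 0.61 on slide 1 and -0.12 on slide 2. Ligand-gated channels had a mean of 0.02 over 12 probes, which was negative with normexp, quantile normalization or median centring. Ion channels had a mean of 0.08 over 9 probes, with CUST_2284 at 0.63 and a standard error of 0.27. Synaptic vesicle proteins had a mean of -0.03 over 18 probes, with a synaptic vesicle transporter (CUST_1497) at -0.37 and a standard error of 0.21. EF-hand calcium-binding proteins had a mean of -0.01 over 27 probes, positive with normexp. In opposite directions stood CUST_1846 at -0.33 with a standard error of 0.09 and CUST_100 at 0.26 with a standard error of 0.11. Cyclic nucleotide and nitric oxide signalling had a mean of -0.06 over 11 probes and protein kinases a mean of 0.07 over 42. Of the 2 neuropeptide probes, an insulin family probe (CUST_666), whose family holds the brain hormone bombyxin, was lower with a difference of -0.22 and a standard error of 0.09, and a pyrokinin probe (CUST_1650) differed by -0.04 with a standard error of 0.20.

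Heat shock proteins and chaperones, which a handling stress would reach, had 6 of 12 probes higher and a mean of -0.04, and an Hsp70 probe (CUST_1217) differed by -0.21 with a standard error of 0.12. The antimicrobial list by family number had a mean of -0.34 over 8 probes, again with -1.61 on slide 1 and 0.91 on slide 2. Takeout and hormone binding proteins had 8 of 9 probes lower and a mean of -0.07, with 0.14 on slide 1 and -0.36 on slide 2. Detoxification enzymes had 19 of 37 probes higher (mean 0.23, median 0.01), with a P450 probe (CUST_2266) at 0.49 and a standard error of 0.14. With normexp the mean was 0.092 and CUST_2266 stood at 0.096, while 1 member passed over the list alone, and the mean was 0.038 over the probes above background on all 10 arrays. Oxidative phosphorylation had 7 of 9 probes lower (mean -0.06), and ribosomal proteins had 20 of 33 lower (mean -0.01, positive with quantile normalization).

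Families of other tissues were read in the same way. Cuticle and chitin families had 16 of 39 probes higher and 23 lower (mean -0.05). CUST_1009 and CUST_272 rose when adjusted over the list alone (limma adjusted p = 0.0197 each), and no member of the list was called without stimulated replicate 3, 4 or 5, without both control replicate 4 and stimulated replicate 5, with normexp, alone or with slide as a block, with no filter, with the trended robust variance, with the title numbers as a block or on slide 1 alone. With slide as a block 4 members of the cuticle and chitin list were called over the list alone, and they were split in direction. CUST_1009 and CUST_272 were higher in that fit, by 0.37 and 0.40, and the cuticle protein probes CUST_2360 and CUST_328 were lower, at -0.71 and -0.24. Muscle families had a mean of 0.28 over 10 probes, 0.57 on slide 1 and 0.01 on slide 2 (exact permutation p = 0.246). For a myosin tail probe (CUST_612), control replicate 4 stood at 3.16, above the other controls at 1.01 to 2.49, and stimulated replicate 5 at 1.64, below the other stimulated arrays at 2.33 to 3.58. The same layout was seen in a P450 probe (CUST_1003) and a calponin probe (CUST_1200), both picked after their values were seen. Antennal and olfactory families had a mean of -0.16 over 7 probes, 0.22 on slide 1 and -0.58 on slide 2. Without control replicate 2 the antennal and takeout lists passed camera at the preset correlation (adjusted p = 0.00397 and 0.0439) but not with an estimated correlation (adjusted p = 0.282 for both). Over 27 alternatives the preset adjusted p of the antennal list ran from 0.000363 to 0.991 and that of the takeout list from 0.00646 to 0.996. Eye families had a mean of -0.04 over 14 probes, and 2 serpin probes a mean of -0.10.

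**Figure D4:**
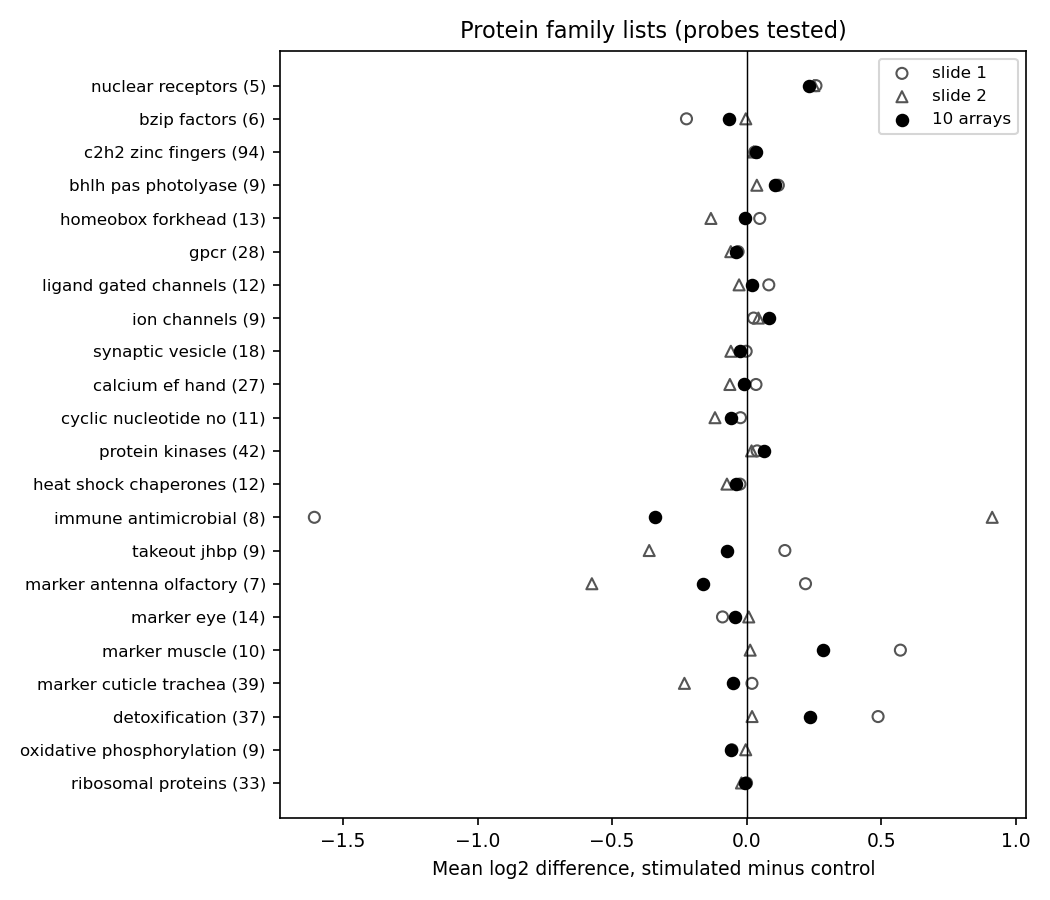
Mean log2 difference, stimulated minus control, of 22 protein family lists, with the number of tested probes in brackets. Black points are the means over 10 arrays and open symbols the differences within slide 1 (circles) and slide 2 (triangles). The antimicrobial list stands at -1.61 on slide 1 and 0.91 on slide 2, and no list passed the set test.

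**Figure D5:**
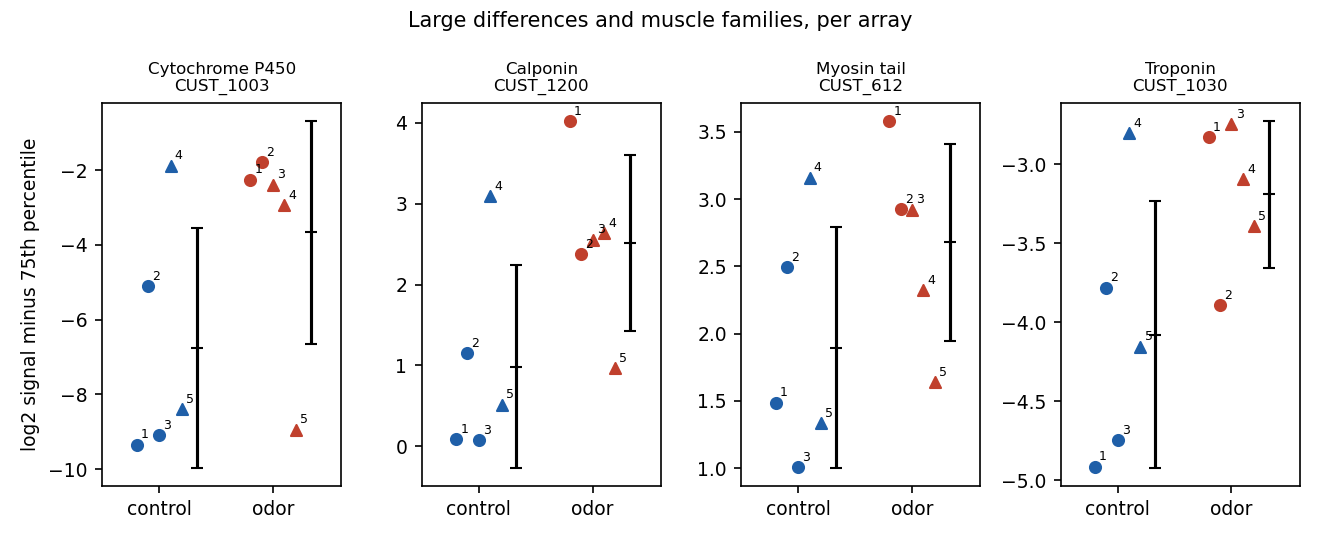
Log2 signal minus the 75th percentile of the array for a P450, a calponin, a myosin tail and a troponin probe, with a point per array numbered by replicate (circles slide 1, triangles slide 2) and group mean ± SD in black, n = 5 per group. Control replicate 4 was the highest control in every panel, and stimulated replicate 5 was the lowest stimulated array in all but the troponin panel, where stimulated replicate 2 was lowest.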

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

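Of the tests in this part, those of the probe count with slide as a block, of both counts over splits within slides and of the exchanged labels were chosen after the result was seen. An array far from the other 4 of its group was found in 7 of 196 groups of 5 values among the named probes and the family list means, and chance gives about 1 in 20. Control replicate 4 was the array in 4 of the 7. Its cuticle protein probe CUST_272 stood at -3.67 against -3.41 to -3.33 in the other controls (gap over range 0.758), its amino acid transporter probe CUST_843 at -5.14 against -5.51 to -5.41 (0.734), its leucine zipper probe CUST_1230 at -0.41 against -0.19 to -0.11 (0.740), and its ATP synthase family probe CUST_2239 at 2.28 against 2.49 to 2.57 (0.726). Control replicate 2 was low for the sequence cluster probe CUST_2034, at -4.26 against -3.81 to -3.68 (0.770). Stimulated replicate 2 was high for the serpin probe CUST_2366, at -1.44 against -1.71 to -1.70 (0.959). Stimulated replicate 5 had the highest mean of the heat shock and chaperone families, at 0.53 against 0.43 to 0.45 (0.814).

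The lack of probes past the threshold was set against slide and chance. With slide as a block, limma still put 0 probes past the adjusted threshold, which argues against the slide difference as the whole reason. Of 100 drawn splits of the 126 possible, 21 gave at least the 490 probes of the real split at an unadjusted p under 0.05, the real one included. The highest other, 6333 probes, was the split that parts the slides, which points to a structure of the samples (1047 probes for the real split with the block). Control replicates 1, 2 and 3 with stimulated replicates 1 and 3 against the rest gave 2148. Splits that divide the slides unevenly thus raise this count, so it neither excludes chance nor shows it. Among splits that keep 2 stimulated arrays on slide 1 and 3 on slide 2, 5 of 100 gave as many as those 1047, the real one included, so chance was not excluded there either (highest other 1219, of which 36 passed the adjusted threshold). Of the same 100 splits, 4 separated as many probes as the 96 of the real one (highest other 180), a small share. But this was the last of 3 counts. The count over all splits could not decide on chance, and the other within slides did not exclude it. Chance therefore stays open, as do position on the slide, nearly the same as group, and a response to odor, both untested.

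Of 44 probes over 2-fold higher after odor, 20 had control replicate 4 above all other controls and stimulated replicate 5 below all other stimulated arrays, such as the P450 probe CUST_1003 at -1.88 against -9.34 to -5.09, and -8.94 against -2.94 to -1.78. CUST_1003 was well above background on 2 control and 4 stimulated arrays only, so its lowest values were dim. Another 44 probes were over 2-fold lower, and this layout was counted neither among them nor over all probes. Muscle left on the dissected brains is a candidate explanation, though not a specific one: the mean of the 10 muscle family probes in control replicate 4 lay 0.17 above the highest other control, and that in stimulated replicate 5 differed by -0.32 from the lowest other stimulated array, but 3 of 24 family lists showed this layout, with takeout at gaps of 0.60 and -0.17 and detoxification at 0.13 and -0.43, and cuticle stood 0.40 above in control replicate 4. The muscle members differed in this layout. The myosin probes CUST_611 and CUST_612 showed it in full, and the troponin probes CUST_1029 and CUST_1030 in control replicate 4 only. Another myosin probe, CUST_3042, showed neither part. It read -0.05 in control replicate 4 against 0.08 in control replicate 3, and -0.10 in stimulated replicate 5 against -0.34 in stimulated replicate 2. The tropomyosin probes CUST_1583 and CUST_1584 and the actin probe CUST_81 showed the layout in stimulated replicate 5 only. The abundant tropomyosin probe CUST_1586 read 4.52 in control replicate 4, against 4.62 in control replicate 2 and 3.02 to 3.19 in the other controls. Its 3.29 in stimulated replicate 5 was the lowest stimulated value. The actin probe CUST_1919, of a family that brain also expresses, parted by slide. It read 2.49 to 2.61 on slide 1 and 2.18 to 2.28 on slide 2, so it cannot speak for or against muscle. Exchanged labels of control replicate 4 and stimulated replicate 5, an idea taken from the 20 probes above, cannot be told apart from muscle left on the brains. With slide as a block the exchanged split gave 15 probes past the adjusted threshold, against 0 as labelled and 36 in another split. At an unadjusted p under 0.05, however, it gave 617, against 1047 as labelled. A response to odor alone would not place control replicate 4, an untreated pool, with the stimulated arrays, and other differences between pools were not tested.

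Antimicrobial peptide probes spread widely between pools of one group. The mean of 5 cecropin and attacin probes ran from -6.00 to -1.45 in controls and from -6.15 to -3.36 in stimulated brains. The SD within slides was 1.06 times the SD over all arrays. Both groups were pooled in that SD and their difference ran opposite ways on the slides, so it cannot exclude slide. Stimulated pools stood at -6.15 and -5.23 on slide 1 and at -4.43 to -3.36 on slide 2. Control pools stood at -5.32 to -1.45 on slide 1 and at -6.00 and -4.13 on slide 2. Differences between pools in the immune state of the moths may account for the spread, and no biological explanation was tested.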

How the results depend on the processing

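The combinations with the slide block, the slides alone and the joint omission of control array 4 and stimulated array 5 were chosen after seeing the data, the last for their values. The lists by family number were chosen after the names were seen and before any signal was compared. The number of probes past the adjusted threshold was 0 in every setting but 1: that joint omission called 1 probe (CUST_4457, 4.04, adjusted p = 0.0104). At an adjusted p under 0.1, array weights called 3297 probes. Their weights, from 0.41 to 2.59, were above 1 for control arrays 1 to 3, all on slide 1, and stimulated arrays 3 to 5, all on slide 2, so that fit set mostly slide against slide, and array weights with slide as a block called 0. Under that threshold slide as a block with the trended robust variance called 3 and with normexp 2. Counts at an unadjusted p under 0.05 ran from 342 to 728 with an array left out. The 20 probes of smallest p reversed in 0 of the settings run. They were picked by p on these same arrays, which favours a kept sign, and no share over all probes was computed. A change of filter, the value table or the trended robust variance leaves a log2 difference as it was. Of 1993 values of named probes over 27 settings 52 changed sign, and of 810 list means 67. Hr38 alternatives and the mean of a gene's probes were not run, as no probe carries a gene name. Surrogate values limit dim probes most. Where values below differ, the cause was not tested.

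Of fixed lists, 1 passed camera at the preset correlation on slide 1 alone, 1 on slide 2 alone and 1 with the joint omission, the antimicrobial list each time, and 0 to 1 with an array left out. Of family lists, 1 passed on each slide alone, the antimicrobial list, and 0 to 2 with an array left out. None of these camera calls, nor those with a replicate block, held with an estimated correlation (smallest adjusted p = 0.224). Members of fixed lists called over the list alone numbered 1 as reported, 0 with normexp and on each slide alone, 3 with array weights, 2 with the joint omission, and 1 to 2 with an array left out. Members of family lists called over the list alone numbered 2 as reported, 1 with normexp, quantile normalization or slide 2 alone, 4 with median centring, 0 with no filter or the trended robust variance, 33 with array weights, 5 with slide as a block, alone or with the trended robust variance or array weights, 8 with the joint omission, and 0 to 6 with an array left out. They numbered 3 with the source name numbers as a block, with slide as a block and normexp, and on slide 1 alone.

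Sign changes in log2 differences were these, with list means named by list. With normexp, they were CUST_1199 0.026, CUST_307 -0.081, CUST_308 -0.084, CUST_1430 -0.0057, CUST_3597 0.042, fixed synapse -0.037, homeobox 0.040, ligand-gated channel -0.00070 and EF-hand 0.0038. Quantile normalization gave fixed synapse -0.0064, fixed eye -0.0073, ligand-gated channel -0.015 and ribosomal 0.011. Median centring gave CUST_308 -0.022, fixed synapse -0.015, fixed eye -0.014 and ligand-gated channel -0.0074. No filter gave EF-hand 0.0075, takeout 0.20 and oxidative phosphorylation 0.010, and the filter on all 10 arrays gave homeobox 0.042. Array weights gave CUST_307 -0.059, CUST_2737 0.52, CUST_3597 0.25, fixed chaperone 0.0096, fixed synapse -0.041, leucine zipper 0.073, homeobox 0.061, ligand-gated channel -0.012, EF-hand 0.0097, takeout 0.025 and cuticle family 0.072. Slide as a block gave CUST_1205 -0.025 and fixed eye -0.044, the same with the trended robust variance. With normexp it gave CUST_1205 -0.031, CUST_308 -0.065, CUST_1430 -0.015, fixed synapse -0.0088, fixed eye -0.013 and homeobox 0.0055, and with array weights CUST_1205 -0.054, CUST_308 -0.0091 and fixed eye -0.041.

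Slide 1 alone gave CUST_715 -0.0032, CUST_1430 -0.11, fixed eye -0.14, homeobox 0.049, EF-hand 0.035, takeout 0.14, antennal 0.22 and cuticle family 0.020. Slide 2 alone gave CUST_1230 0.021, CUST_2323 -0.12, CUST_567 -0.066, CUST_926 -0.035, CUST_1650 0.20, CUST_18 0.47, CUST_3402 -0.41, CUST_1205 -0.15, CUST_308 -0.025, CUST_2737 1.67, fixed synapse -0.0020, fixed antimicrobial 1.31, ligand-gated channel -0.028, neuropeptide 0.051, antimicrobial family 0.91 and eye family 0.0080. The joint omission gave CUST_308 -0.029, CUST_1430 -0.0010, CUST_3597 0.013, CUST_3270 0.016, EF-hand 0.0017, takeout 0.18 and cuticle family 0.12. With an array left out, the ranges of results that changed sign were CUST_1650 -0.23 to 0.035, CUST_1205 -0.061 to 0.10, fixed antimicrobial -1.11 to 0.022, antimicrobial family -0.66 to 0.061, CUST_308 -0.045 to 0.054, fixed eye -0.035 to 0.077, CUST_3270 -0.092 to 0.0020, ribosomal -0.019 to 0.0019, CUST_3597 -0.085 to 0.089, homeobox -0.046 to 0.038, EF-hand -0.024 to 0.0057, takeout -0.21 to 0.10, cuticle family -0.14 to 0.080, fixed synapse -0.0074 to 0.044 and ligand-gated channel -0.023 to 0.036.

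Replicate numbers, used as a block, did not clearly pair the pools. In the numbering of the source names, deviations of same-numbered arrays correlated at 0.02, 0.29, -0.43, 0.23 and 0.42 across probes. Only the pair at -0.43 lay across slides, so these values also carry the slide difference. With slide taken out as well they were -0.45, -0.06, -0.16, -0.12 and 0.12. Before that step the own number was the best match for 2 of 5. The block called 0 probes in either numbering, with 913 and 789 probes at an unadjusted p under 0.05. The block by title numbers left out control replicate 2 and stimulated replicate 1, whose title numbers have no match in the other group. In that fit 2 family lists passed camera at the preset correlation, takeout and antennal, as they did without control replicate 2 alone. Neither passed camera with an estimated correlation (adjusted p = 0.412 each). By fry 3 lists passed, these and nuclear receptors (adjusted p = 0.0310 each). Nuclear receptors did not pass camera (adjusted p = 0.386, and 0.628 with an estimated correlation). In that fit 5 members of family lists passed over the list alone. Without control replicate 2 and stimulated replicate 1, that fit also turned CUST_308 to -0.051, CUST_2737 to 0.28, and the antimicrobial means to 0.10 (fixed) and 0.11 (family).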

Other observations

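Some further probes had large differences that did not pass over all probes, and they were picked after their values were seen. A probe of the class II glutamine amidotransferase family (CUST_2173) had a difference of -1.47 with a standard error of 0.38 (limma adjusted p = 0.980), with -1.55 on slide 1 and -1.53 on slide 2. With slide as a block, the family-named probe with the smallest p was an insect cuticle protein (CUST_2360), with a difference of -0.71 and a standard error of 0.09 (adjusted p = 0.111), at -0.63 on slide 1 and -0.80 on slide 2, opposite in sign to the cuticle probe CUST_272. A calponin probe (CUST_1200), of a family of actin-binding muscle proteins, was higher by 1.53 with a standard error of 0.67, but by 2.76 on slide 1 and 0.25 on slide 2. Among probes left out for low signal, 1 was well above background on 4 stimulated and 0 control arrays (CUST_10691), and 0 showed the opposite.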
